A study of Mus musculus with 12 samples.

How the data were processed

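The deposited table held the authors' quantification of 12 libraries, namely an estimated count (an RSEM expected count) and an FPKM value per gene and library. Its 22013 entries carry Ensembl mouse gene identifiers, and 112 entries without a symbol held at most 0.0124% of the counts of any library. Per the submitters' processing notes HISAT2 2.1.0, StringTie 1.3.1, Bowtie2 2.2.8 and RSEM were run before deposition; alignment and quantification were not repeated here. The genome build and gene annotation are not given in the sources used here, so no coordinates are printed. For 21827 identifiers the GENCODE vM21 reference (assembly GRCm38) gave a name, and chromosome and neighbour order were taken from it alone. The estimated counts were deposited to 2 decimals; 10.4% of the values, zeros included, were not whole numbers as printed, and all were rounded for the count tests. All 12 libraries were kept, including knockout glycine 5, labelled with 80 mg/kg per day where the other glycine libraries carry 800.

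Group and replicate follow the sample labels. The labels do not say that the 3 libraries of a group come from separate animals. The libraries may be technical replicates, such as separate preparations of one sample. P-values of genes and lists rest on the spread between libraries labelled as replicates. Fisher p-values of overlaps take genes as independent, which they are not. Library totals ran from 14.5 M to 24.3 M estimated counts. Genes were filtered with filterByExpr, leaving 13928, and scaled by TMM. Differential expression was tested with the edgeR quasi-likelihood test (robust fit, 1 model with 4 groups) in 5 contrasts: glycine against saline in each genotype, knockout against wild type under each treatment, and the glycine by genotype interaction. Adjusted p is the Benjamini-Hochberg value over the 13928 genes, and a gene is said to rise, fall or change only below 0.05. Log2 fold changes carry the default prior count of the edgeR fit and are given with standard error (SE). Mean log2 CPM levels of lists carry a prior count of 2. Other levels are CPM (counts scaled to a common library total), mean and SD of the 3 libraries of a group. Fold changes against a group at 0 counts are printed as at least the fold from 3 counts over that group, and ratios over 1 to 3 counts with a 95% interval; both cover counting error only. With 3 libraries against 3, complete separation of a gene's values arises by chance in 10% of genes, and the smallest exact p is 0.1.

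Genes are named by a fixed rule. Glra2 comes first, in every library. Each pairwise comparison then gives the 8 largest rises and 8 largest falls among genes with adjusted p below 0.05, a symbol other than a predicted locus, a mean of at least 5 CPM in the higher group and no overlap between the groups. Each fixed list gives up to 4 members with the smallest adjusted p below 0.05, or otherwise 1 member with the smallest p. Nos3, Cdh5 and Pecam1 are always included, and the interaction adds the 6 genes with the smallest p. Of the list members taken in this way the text prints examples, picked after the results were seen. A few further genes that met this rule are not reported here, and no other gene takes their place.

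Before the data were examined, 32 gene lists were fixed: nitric oxide and vasodilation; glycine receptors, transport and metabolism; calcium and membrane potential channels; endothelial identity; shear-responsive and KLF2/KLF4 genes; adhesion molecules and NF-kB inflammation; oxidative stress and antioxidant defence. Further lists were extracellular matrix and fibrosis; endothelial-to-mesenchymal transition regulators; angiogenesis and VEGF signalling; proliferation; interferon response; unfolded protein response; hypoxia and glycolysis. Metabolic and stress lists were mitochondrially encoded genes, nuclear respiratory chain, cholesterol biosynthesis, fatty acid uptake and oxidation, and immediate-early and heat-shock genes. Cell-type lists were smooth muscle, fibroblast, macrophage and monocyte, T and NK cell, B cell, neutrophil, erythroid and platelet, adipocyte, mesothelial and epithelial, Schwann cell and neuron, skeletal and cardiac muscle, and lymphatic endothelium, with sex-linked genes last. Lists were tested with camera at a preset correlation of 0.01 (Benjamini-Hochberg over 160 tests), and beside it with a correlation estimated from the data and with fry. Members were also adjusted over their list alone. In addition 337 KEGG pathways of 10 to 500 genes were tested. A thymocyte, a clock-gene and an immunoglobulin constant-region list were chosen after the results were seen.

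Settings fixed before the data were examined comprised size factors in place of TMM, DESeq2, both filters, FPKM with limma-trend (pseudocounts 1 and 0.1), a fold-change bound, the smooth muscle and fibroblast level as a covariate, each library left out in turn, only the compared groups in the model, and the replicate number as a block. Leaving out the 13 mitochondrial genes and using the macrophage level as a covariate were chosen after the data were seen. Counts were also simulated from each gene's mean over all 12 libraries and its edgeR dispersion, with no group differences but the changes put in. At 4-fold, recovery was 48% (glycine in wild type), 46% (glycine in knockout), 54% (knockout under saline), 60% (knockout under glycine) and 28% (interaction) of changed genes. At 2-fold, recovery was 8%, 22%, 8%, 18% and 2% in the same order. False calls made up 2.60 to 3.85% with edgeR, 0 to 7.08% with limma-trend on log2 CPM and 21.2 to 30.9% with DESeq2. Because these counts follow edgeR's own model, the rates do not rank the methods on the real counts. Software was R 4.3.3, edgeR 4.0.16, limma 3.58.1, DESeq2 1.42.0, data.table (version 1.17.8), Python 3.11.15 and matplotlib 3.10.9.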

Results

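The series sampled aortic endothelial cells, by the labels, from mice given angiotensin II and then saline or glycine by intraperitoneal injection. Both treatments were applied to wild-type mice and to mice lacking Glra2, which encodes the α2 subunit of the glycine receptor. The study's stated subject is how that receptor bears on endothelium-dependent vasodilation and on endothelial nitric oxide synthase, the product of Nos3. Each of the 4 groups has 3 RNA-seq libraries.

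Glra2 (ENSMUSG00000018589), the targeted gene, had 0 counts in all 12 libraries, including the 6 from wild-type mice. The glycine receptor genes Glra3 and Glra4 also had 0 counts throughout, where 3 counts would equal 0.118 to 0.279 CPM. Glra1 had at most 3 counts in a library, and Glrb, the receptor's β subunit, had 69, 40 and 5 counts in wild-type saline 1 to 3, 0, 19 and 48 in wild-type glycine 4 to 6, 0, 0 and 63 in knockout saline 1 to 3, and 54, 0 and 16 in knockout glycine 4 to 6. The genotype labels therefore cannot be checked by expression of the target.

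Nos3 (ENSMUSG00000028978) was measured at a low level in every group: 9.08 ± 2.98 CPM in wild-type saline, 4.97 ± 3.24 in wild-type glycine, 5.52 ± 1.06 in knockout saline and 6.47 ± 4.25 in knockout glycine. Its lowest libraries were wild-type glycine 4 (1.23 CPM) and knockout glycine 5 (1.57 CPM), and it passed the threshold in no comparison. Its log2 fold change with glycine was −0.87 ± 0.69 SE in wild type (adjusted p = 0.737) and 0.23 ± 0.68 in knockout (0.977), with an interaction of 1.09 ± 0.97 (0.724). Between genotypes it was −0.71 ± 0.69 under saline (0.619) and 0.38 ± 0.68 under glycine (0.908). Pecam1 and Cdh5, 2 endothelial junction genes, were more abundant than Nos3, at 137 ± 23.2 and 31.5 ± 8.30 CPM in wild-type saline.

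Genes of other cell types were abundant in all groups. In wild-type saline the fibroblast genes Ccdc80 and Lum averaged 2949 ± 933 and 2605 ± 346 CPM, and the macrophage gene Lyz2 averaged 3034 ± 615. Mitochondrially encoded genes took 55.6 ± 7.96% of the counts in wild-type saline, 35.1 ± 4.12% in wild-type glycine, 39.9 ± 9.12% in knockout saline and 30.6 ± 4.92% in knockout glycine. Haemoglobin genes took 1.5 ± 0.411%, 2.93 ± 1.99%, 4.51 ± 1.75% and 1.81 ± 0.755% in the same order. Correlations between libraries were 0.852 to 0.917 within groups and 0.818 to 0.886 between groups. The leading component, with 20.3% of the variance, placed all wild-type libraries on one side and all knockout libraries on the other. The second, with 15.1%, set wild-type glycine 4 apart (score −136, others −19.6 to 57.1). That library had the fewest genes with a count (12945, others 13387 to 14397), and 2.90% of the genes with at least 20 counts in 8 or more other libraries had 0 counts in it (others 0.144 to 1.38%).

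**Figure D1:**
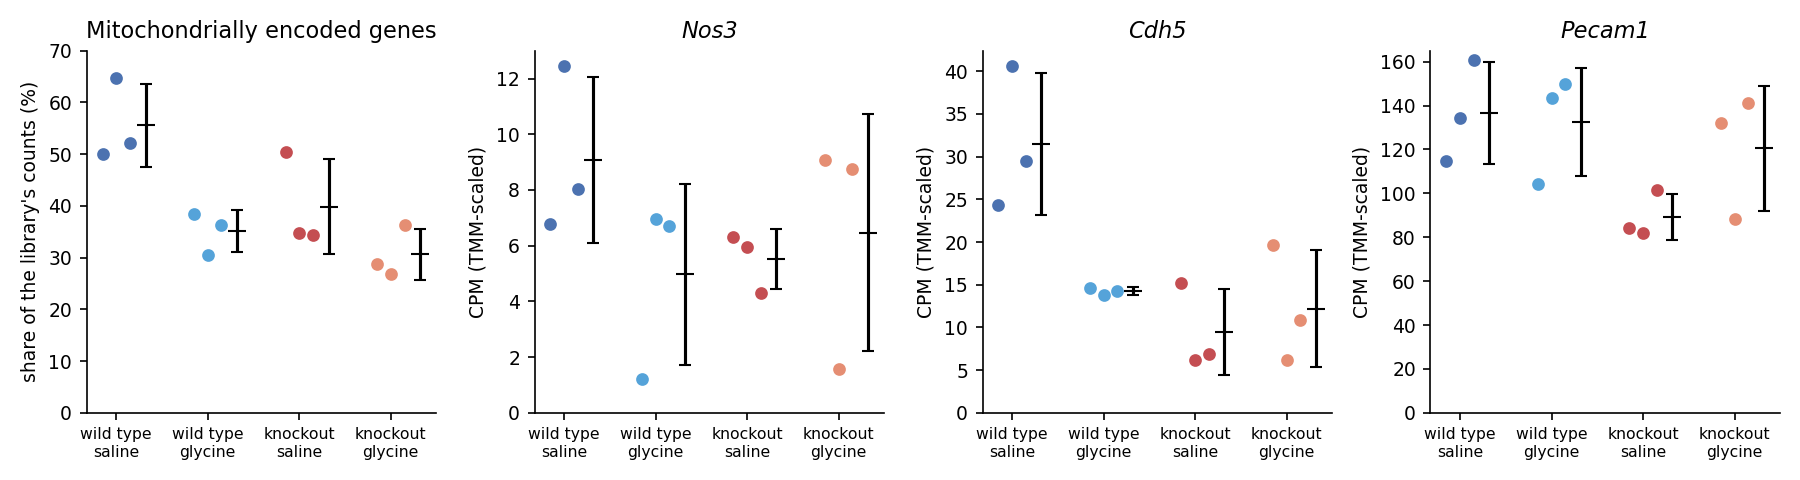
Share of counts from mitochondrially encoded genes (%) and levels of Nos3, Cdh5 and Pecam1 (CPM) in the 4 groups; each point is 1 library and the black bar is the mean ± SD of 3. The mitochondrial share is highest in wild-type saline (55.6%) and Cdh5 stands higher there (31.5 CPM) than in knockout saline (9.42 CPM).

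What does glycine change in wild-type mice? Among genes that passed, the most frequent listed type was macrophage, with 10 of 22 listed members higher (list adjusted p = 0.0464 with an estimated correlation). Mrc1, the mannose receptor of tissue macrophages, rose, as did the complement gene C1qa and the lysozyme gene Lyz2. Kdr, the main receptor for vascular endothelial growth factor, and Ccl21a, a chemokine of lymphatic endothelium, fell. Igha, the constant region of immunoglobulin A, went from near absence to a clear signal. Of these genes Mrc1 and Igha kept their calls whichever library was left out. C1qa and Lyz2 lost them in 4 of 6 such fits, Kdr in 3 and Ccl21a in 1 (highest adjusted p 0.0722 without wild-type glycine 6, 0.0777 without wild-type saline 1, 0.0865 without wild-type saline 3 and 0.0537 without wild-type glycine 6).

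Of 13928 genes, 193 passed the threshold (138 higher, 55 lower), with 1669 at unadjusted p below 0.05 and 150 changed at least 2-fold. Rises made up 71.5% of these calls on counts and 95.3% on the authors' FPKM (1047 of 1099), where the median gene also shifted by 0.37 log2. The number of calls was 115 without wild-type saline 1, 80 without wild-type saline 3, 90 without wild-type glycine 5 and 83 without wild-type glycine 6. With only the 2 compared groups in the model it was 31 (18 higher, 13 lower).

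The macrophage and monocyte list had 10 of 22 members higher and none lower (17 when adjusted over the list alone; median log2 fold change 0.74). Its list test gave adjusted p = 7.88e-19 and adjusted p = 0.0464 with an estimated correlation. Mrc1 (ENSMUSG00000026712) rose from 123 ± 24.8 to 301 ± 33.6 CPM (log2 fold change 1.29 ± 0.19 SE, adjusted p = 0.00513), a call kept when any library was left out. C1qa rose by 1.03 ± 0.19 (0.0149), Fcgr1 by 1.54 ± 0.29 (0.0155) and Lyz2 by 0.91 ± 0.18 (0.0200). Those calls ended in 4 of 6 leave-one-out fits for C1qa and Lyz2 and in 2 for Fcgr1, with the highest adjusted p without wild-type glycine 6 for C1qa (0.0722) and without wild-type saline 1 for Fcgr1 and Lyz2 (0.0646 and 0.0777). Among KEGG pathways, Lysosome had 10 genes higher and 1 lower of 122 and Phagosome 12 higher of 140. Pathway calls numbered 15 at the preset correlation and 0 with an estimated one.

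Some antibody genes rose beside the macrophage genes. Igha (ENSMUSG00000095079) rose from 0.239 ± 0.206 to 70.6 ± 15.4 CPM (log2 fold change 8.32 ± 0.37 SE, adjusted p = 1.33e-08). Igkc, the kappa constant region, rose from 116 ± 9.45 to 312 ± 120 CPM (1.43 ± 0.25, 0.0104). The B cell list had 3 of 17 members higher (4 over the list alone; median 0.57, adjusted p = 0.00130, and adjusted p = 0.318 with an estimated correlation). Its call ended without wild-type saline 3. The variable segments Ighv4-1 (5.69 ± 0.75, 0.00342), Igkv19-93 and Igkv8-30 were also among the largest rises; such segments share reads with near-identical copies, which leaves their single levels uncertain. Igkv19-93 lost its call in 3 of 6 leave-one-out fits (highest 0.087, without wild-type saline 1) and Igkv8-30 in 5 (0.149, without wild-type saline 3). Tmem273, a small membrane protein gene, rose from 0.104 ± 0.0945 to 8.27 ± 6.91 CPM. The other genes among the largest rises lost their calls in part of the 6 fits: the phosphatase gene Ptpn22 (adjusted p = 0.0193) in 2 and the kinase subunit gene Pik3r5 (0.0481) in 4 (highest 0.0838 and 0.149, both without wild-type saline 3), and the clock gene Nr1d1 (0.0479) in 5 (0.119, without wild-type glycine 5).

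The largest falls included Cnmd, Wif1, Sox9 and Meox1. For these genes, and for the macrophage and antibody genes above, a changed share of cells cannot be told apart from a change in expression. Cnmd, an inhibitor of vessel growth in cartilage, fell from 22.9 ± 13.3 to 0.748 ± 0.664 CPM (log2 fold change −4.88 ± 0.84 SE, adjusted p = 0.0102). Wif1, a secreted Wnt inhibitor, fell from 44.7 ± 11.3 to 3.68 ± 3.16 CPM (−3.62 ± 0.60, 0.00946). The homeobox gene Meox1 (−2.33 ± 0.39, 0.00953) and the laminin gene Lamb1 (−2.28 ± 0.32, 0.00421) fell in every leave-one-out fit. Sox9, the chondrocyte regulator (−2.70 ± 0.50, 0.0153), lost its call in 3 of 6 such fits (highest 0.0945, without wild-type saline 3). Gsta3 (−3.10 ± 0.58, 0.0153) and Smim41 (−2.87 ± 0.60, 0.0269) lost theirs in 3 and 4 fits (highest 0.0838 without wild-type saline 3 and 0.127 without wild-type glycine 6). The fibroblast list had 3 of 20 members lower and none higher (8 lower and 4 higher over the list alone; median −0.21, adjusted p = 0.0187, and adjusted p = 0.539 with an estimated correlation). It includes Ccdc80 (−1.08 ± 0.20, 0.0155) and Tcf21. On FPKM its median was 0.26, opposite in sign but below the median of 0.37 of all genes there. The list call ended in 4 leave-one-out fits, among them that without wild-type saline 1. Ccdc80 lost its call in 4 of 6 and Tcf21 in 5 (highest 0.0841 and 0.102, both without wild-type saline 3). In the opposite direction, 2 of 32 matrix genes rose, Lox (1.32 ± 0.25, 0.0164) and Spp1 (1.55 ± 0.31, 0.0236), in a list that did not pass (0.0889). Lox lost its call in 3 of 6 fits (highest 0.0733, without wild-type glycine 6) and Spp1 in 4 (0.0958, without wild-type saline 1).

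Among endothelial genes, Kdr fell from 114 ± 37.7 to 38.7 ± 2.22 CPM (log2 fold change −1.56 ± 0.30 SE, adjusted p = 0.0160; lost in 3 of 6 leave-one-out fits, highest 0.0865 without wild-type saline 3). It was the 1 member of 29 lower in the endothelial identity list (4 over the list alone; median −0.64, adjusted p = 2.56e-09, and adjusted p = 0.143 with an estimated correlation). Cdh5 did not pass (−1.14 ± 0.43, 0.275) and Pecam1 was level (−0.05 ± 0.21, 0.976). The angiogenesis list, which shares Kdr, had a median of −0.89 on counts and 0.01 on FPKM (adjusted p = 2.58e-05, and adjusted p = 0.0738 with an estimated correlation). All genes had a median of 0.37 on FPKM. Ccl21a fell from 175 ± 33.3 to 81.1 ± 8.05 CPM (−1.11 ± 0.19, 0.00969; lost in 1 fit, 0.0537 without wild-type glycine 6). The lymphatic list had 1 of 10 lower (3 over the list alone; median −0.79, adjusted p = 0.000312, and adjusted p = 0.0464 with an estimated correlation). Wild-type glycine 4 had the lowest mean log2 level of its group in the endothelial identity list (3.85, against 4.50 and 4.39) and the lymphatic list (3.16, against 4.77 and 4.30). Without it both list calls stayed at the preset correlation.

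Of the mitochondrially encoded genes 4 of 13 fell, among them mt-Nd5 (log2 fold change −1.37 ± 0.27 SE, adjusted p = 0.0225), mt-Cytb and mt-Co1. Their calls ended in 3, 4 and 4 of 6 leave-one-out fits, with the highest values without wild-type glycine 5 (0.107, 0.177 and 0.194). The list median was −1.12, 12 members were lower over the list alone, and the list test gave adjusted p = 3.85e-17 and adjusted p = 0.135 with an estimated correlation. The oxidative stress list (median 0.26, adjusted p = 0.000283, and adjusted p = 0.131 with an estimated correlation) and the unfolded protein list (0.30, adjusted p = 0.00130, and adjusted p = 0.135 with an estimated correlation) moved up with no single member passing. The adhesion and NF-kB list was higher too (adjusted p = 0.00660, and adjusted p = 0.420 with an estimated correlation), led by Ccl2 (1.28 ± 0.24, 0.0167) and Tnf (2.29 ± 0.48, 0.0269). The adipocyte list was higher with Car3 (1.13 ± 0.22, 0.0172, list adjusted p = 0.00881, and adjusted p = 0.235 with an estimated correlation) and the fatty acid list lower (adjusted p = 0.0310, and adjusted p = 0.349 with an estimated correlation). The adhesion and adipocyte list calls ended without wild-type saline 3, the adhesion one also without wild-type glycine 5. The fatty acid call ended in 4 fits, among them that without wild-type saline 1. On FPKM the fatty acid median was 0.28, opposite in sign but below the median of 0.37 of all genes there. Single genes lost their calls too: Ccl2 in 2 of 6 fits and Car3 in 1 (highest 0.0721 and 0.0698, without wild-type saline 3) and Tnf in 4 (0.118, without wild-type glycine 6).

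In the nitric oxide and vasodilation list 1 of 42 members passed, the endothelin receptor gene Ednrb (log2 fold change 1.37 ± 0.28 SE, adjusted p = 0.0256; lost in 5 of 6 leave-one-out fits, highest 0.106 without wild-type saline 1), and the list did not pass (0.245). None of 23 genes of glycine receptors, transport and metabolism passed (0.814), the nearest being the glutathione gene Gclc (0.90 ± 0.28, 0.166). None of 26 calcium and membrane potential channel genes passed (0.404). The shear-responsive list was flat (0.929) although Hmox1, the haem oxygenase of stress responses, came near (1.06 ± 0.27, 0.0724). The neutrophil gene Camp was at least 10.8-fold higher than in wild-type saline, where it had 0 counts (lost in 3 of 6 fits, highest adjusted p 0.0625 without wild-type saline 3).

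What does glycine change when Glra2 is deleted? In the interferon list 12 of 30 members rose (list adjusted p = 0.0181 with an estimated correlation). Ifit3, Ifit1, Ifi47 and Igtp, which carry out cell-intrinsic defence against viruses and intracellular microbes, rose together. Lck and Trbc2, which encode a kinase and an antigen-receptor chain of T cells, rose as well. Arg1 and Spp1, both made by activated macrophages, fell, though these calls ended in 4 and 2 of 6 leave-one-out fits (highest 0.0927 without knockout saline 2 and 0.0711 without knockout glycine 6).

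The test called 157 genes (129 higher, 28 lower), with 1540 at unadjusted p below 0.05 and 123 changed at least 2-fold. Rises were 82.2% of the calls on counts and 95.7% on FPKM (673 of 703), where the median gene shifted by 0.23 log2. With the smooth muscle and fibroblast level as a covariate 0 genes were called, while all 157 kept their direction. That level itself differed between these groups. The fibroblast list was at 7.73 ± 0.146 mean log2 CPM in knockout saline and 8.16 ± 0.132 in knockout glycine. The smooth muscle list was at 2.48 ± 0.0348 and 3.05 ± 0.132. The covariate therefore takes up part of the contrast, and the lost calls name no source. Fewer genes were called without knockout saline 1 (99), knockout saline 2 (62), knockout saline 3 (65), knockout glycine 5 (57) and knockout glycine 6 (71); knockout glycine 5 is the library with the lower dose label.

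In the interferon list 12 of 30 members rose and none fell (18 over the list alone; median 1.12). The list test gave adjusted p = 2.44e-27 and adjusted p = 0.0181 with an estimated correlation. Ifit3 (ENSMUSG00000074896) rose from 59.8 ± 7.82 to 234 ± 9.36 CPM (log2 fold change 1.97 ± 0.21 SE, adjusted p = 0.000799). Ifit1 rose by 1.64 ± 0.23 (0.00293), Ifi47 by 1.42 ± 0.18 (0.00197) and Igtp by 1.42 ± 0.19 (0.00293), and these calls held whichever library was left out.

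Of 19 listed T cell genes 3 rose (9 over the list alone; median 1.56, adjusted p = 1.36e-12, and adjusted p = 0.0721 with an estimated correlation). Trbc2 (ENSMUSG00000076498) rose from 2.90 ± 0.248 to 45.9 ± 5.51 CPM (log2 fold change 3.98 ± 0.39 SE, adjusted p = 0.000359) and Lck from 10.5 ± 4.65 to 64.2 ± 8.99 CPM (2.61 ± 0.36, 0.00293). Arpp21, a gene of developing thymocytes, was at least 170-fold higher than in knockout saline, where it had 0 counts, but its call ended in 6 of 6 leave-one-out fits (highest adjusted p 0.131, without knockout saline 2). In a thymocyte list assembled after seeing this, 3 of 13 measured members rose here and 0 with glycine in wild type (medians 4.72 and 0.97), and 0 passed the interaction test. Ighg2b rose from 8.59 ± 4.36 to 152 ± 12.9 CPM (4.14 ± 0.70, 0.00874). The other largest rises were mostly immunoglobulin variable segments whose calls depended on single libraries: Ighv7-3 (0.0401), Igkv12-41 (0.0249), Igkv1-117 (0.0313), Ighv9-3 (0.0114) and Igkv19-93 (0.00906) lost theirs in 6, 6, 5, 4 and 1 of 6 fits. The highest adjusted p were 0.156 without knockout glycine 6, 0.125 without knockout saline 2, 0.144 without knockout glycine 5, 0.0828 without knockout glycine 6 and 0.0591 without knockout saline 3. Ogdhl rose too (4.36 ± 0.78, 0.0127; lost in 2 fits, highest 0.0841 without knockout saline 2). The B cell list had 2 of 17 higher (median 0.79, adjusted p = 1.16e-05, and adjusted p = 0.191 with an estimated correlation). The proliferation list moved up with no member passing (median 0.59, adjusted p = 0.000103, and adjusted p = 0.0464 with an estimated correlation).

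Some fibroblast and matrix genes rose in knockout. Mmp3, a matrix-degrading protease, rose from 212 ± 52.9 to 590 ± 63.7 CPM (log2 fold change 1.48 ± 0.20 SE, adjusted p = 0.00293), and the chemokine gene Cxcl12 rose by 1.31 ± 0.22 (0.00824). Serpinf1 rose from 393 ± 27.2 to 884 ± 136 CPM (1.17 ± 0.16, 0.00293) and Col1a1 by 1.63 ± 0.27 (0.00843; lost in 1 of 6 fits, 0.0552 without knockout saline 2). The fibroblast list had 3 of 20 higher (8 over the list alone; median 0.47, adjusted p = 1.68e-07, and adjusted p = 0.167 with an estimated correlation). In the matrix list 6 of 32 rose and Spp1 fell (median 0.33, adjusted p = 0.000240, and adjusted p = 0.294 with an estimated correlation). The smooth muscle list moved up with no member passing (0.62, adjusted p = 0.000706, and adjusted p = 0.135 with an estimated correlation), and Ccl21a rose (0.90 ± 0.19, 0.0290; lost in 5 of 6 fits, highest 0.144 without knockout saline 3).

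Some genes of heart muscle and fat rose as well. For these genes and the T cell and thymocyte genes, a larger share of such cells cannot be told apart from a change in expression. Nppa, the atrial natriuretic peptide gene, rose from 98.9 ± 46.6 to 885 ± 195 CPM (log2 fold change 3.16 ± 0.53 SE, adjusted p = 0.00861) and the cardiac myosin gene Myh6 by 3.49 ± 0.57 (0.00789, lost in 1 of 6 fits, 0.0513 without knockout saline 3). The skeletal and cardiac muscle list had 3 of 16 higher (10 over the list alone; median 1.62, adjusted p = 3.96e-13, and adjusted p = 0.103 with an estimated correlation). Cfd, an adipocyte protease gene, rose from 2.31 ± 1.48 to 26.6 ± 1.06 CPM (3.58 ± 0.40, 0.000981), and Car3 by 1.48 ± 0.22 (0.00434); 3 of 16 adipocyte genes were higher (list adjusted p = 0.0140, and adjusted p = 0.268 with an estimated correlation). KEGG Cardiac muscle contraction was the leading pathway, with 5 of 71 genes higher (adjusted p = 5.63e-08, and adjusted p = 0.644 with an estimated correlation).

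Some macrophage genes fell in knockout. Arg1, arginase 1, fell from 99.5 ± 72.7 to 8.62 ± 2.1 CPM (log2 fold change −3.53 ± 0.65 SE, adjusted p = 0.0156; lost in 4 of 6 leave-one-out fits, highest 0.0927 without knockout saline 2). Lyz2 fell by 0.98 ± 0.18 (0.0146; lost in 3 fits, highest 0.0906 without knockout glycine 5) and Spp1 by 1.81 ± 0.31 (0.0106; lost in 2, highest 0.0711 without knockout glycine 6). Atp7a, a copper transporter gene, fell from 66.5 ± 11 to 20.4 ± 6.10 CPM (−1.70 ± 0.27, 0.00611) and kept its call in all leave-one-out fits. Like every call of this comparison, that of Atp7a ended with the smooth muscle and fibroblast covariate, which takes up part of this contrast. Its log2 fold change ran from −1.98 to −1.26 over all settings. In the macrophage list 3 of 22 members fell and 1 rose (9 and 1 over the list alone; median −0.52, adjusted p = 2.96e-08, and adjusted p = 0.131 with an estimated correlation). The oxidative stress list fell with Hmox1 (−1.29 ± 0.27, 0.0309, list adjusted p = 0.00409, and adjusted p = 0.188 with an estimated correlation), though its median was 0.08 on FPKM. The hypoxia and glycolysis list also changed sign there (median −0.21 on counts and 0.07 on FPKM, adjusted p = 0.000175, and adjusted p = 0.0977 with an estimated correlation). On FPKM both list medians were below the median of 0.23 of all genes. Hmox1 lost its call in 5 of 6 leave-one-out fits (highest 0.153, without knockout saline 3). The other largest falls were Lepr (−2.76 ± 0.54, 0.0226), Pik3r3 (−2.47 ± 0.55, 0.0444), S100a4 (−1.76 ± 0.37, 0.0317), Gpd2 (−1.57 ± 0.35, 0.0424) and Slc25a37 (−1.42 ± 0.31, 0.0401), with calls lost in 4, 5, 5, 6 and 6 of 6 fits. Their highest adjusted p were 0.116 without knockout glycine 5, 0.195 without knockout glycine 6, 0.233 and 0.191 without knockout saline 2 in that order, and 0.192 without knockout glycine 6.

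Several lists moved with no member passing. Lower were the mitochondrially encoded genes (median −0.73, adjusted p = 8.80e-08, and adjusted p = 0.288 with an estimated correlation), the neutrophil list (−0.93, adjusted p = 1.05e-05, and adjusted p = 0.0977 with an estimated correlation) and the erythroid list (−0.81, adjusted p = 1.07e-07, and adjusted p = 0.142 with an estimated correlation). Nuclear respiratory chain genes were higher (0.27, adjusted p = 5.32e-05, and adjusted p = 0.268 with an estimated correlation). Endothelial identity (0.192), angiogenesis (0.292), nitric oxide and vasodilation (0.981) and glycine receptors, transport and metabolism (0.911) did not pass; Pecam1 (0.43 ± 0.21, 0.469) and Cdh5 (0.38 ± 0.43, 0.875) were not changed.

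**Figure D2:**
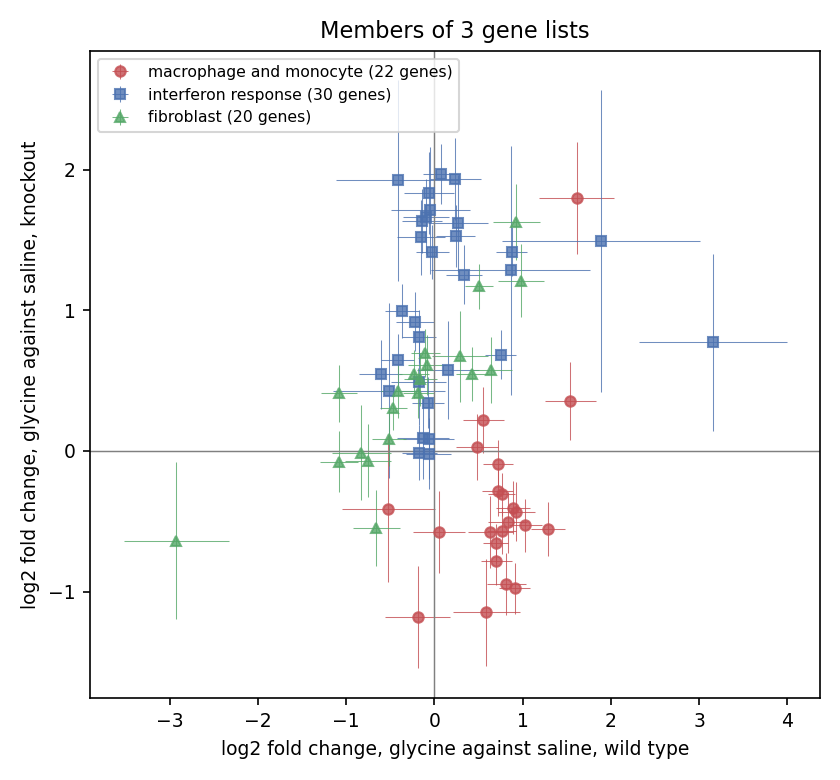
Log2 fold change with glycine in wild type (horizontal) and in knockout (vertical) for measured members of the macrophage (22), interferon (30) and fibroblast (20) lists; points are genes and bars are SE. The macrophage median is 0.74 in wild type and −0.52 in knockout, and the interferon median in knockout is 1.12.

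Does the response to glycine depend on genotype? The direct test of the difference between both glycine effects called 156 genes, 38 with a higher and 118 with a lower effect in knockout, 154 of them by at least 2-fold. Of the macrophage list 10 of 22 members rose with glycine in wild type, while in knockout 3 fell and 1 rose (list adjusted p = 0.131 with an estimated correlation there). Of the interferon list 12 of 30 rose in knockout and 1 in wild type, Ifi47, a call lost in 4 of 6 leave-one-out fits (highest adjusted p 0.0993, without wild-type glycine 6). Unadjusted p was below 0.05 for 1823 genes. Calls fell to 60 without knockout saline 3 and reached 338 without wild-type glycine 4, with 71 to 80 when wild-type glycine 5 (78), wild-type glycine 6 (76), knockout saline 2 (71) or knockout glycine 4 (80), 5 (76) or 6 (75) was removed.

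Macrophage members had a lower glycine effect in knockout in 10 of 22 cases (16 over the list alone; median difference −1.25), with adjusted p = 9.81e-22 for the list and adjusted p = 0.0464 with an estimated correlation. Cfp, which encodes the complement factor properdin, went from 87.9 ± 17.2 to 261 ± 57.7 CPM with glycine in wild type and from 434 ± 38.0 to 234 ± 10.7 CPM in knockout (difference −2.46 ± 0.26 SE, adjusted p = 0.000540). Ms4a4a (−2.71 ± 0.33, 0.00187) and Tmem106a (−1.87 ± 0.23, 0.00187), both macrophage membrane genes, and Mrc1 (−1.84 ± 0.27, 0.00519) rose in wild type and did not pass in knockout. Lyz2 (−1.89 ± 0.25, 0.00210) and Spp1 (−3.37 ± 0.44, 0.00200) rose in wild type and fell in knockout, and Hmox1 (−2.35 ± 0.38, 0.00830) fell in knockout and did not pass in wild type. The KEGG pathway Lysosome had 12 of 122 genes lower (adjusted p = 2.55e-11, and adjusted p = 0.280 with an estimated correlation).

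Interferon members had a higher effect in knockout in 7 of 30 cases (16 over the list alone; median 1.02, adjusted p = 2.16e-12, and adjusted p = 0.0464 with an estimated correlation). The GTPase gene Iigp1 was at 133 ± 19.2 and 52.6 ± 10.3 CPM in wild type under saline and glycine, and at 41.1 ± 8.45 and 195 ± 25.4 in knockout (3.59 ± 0.29 SE, adjusted p = 2.28e-05). Its relative Tgtp2 followed (3.23 ± 0.34, 0.000502), as did Ifit3 (1.89 ± 0.29, 0.00703). Igha had the smallest p (−6.62 ± 0.44, 4.04e-06), at 0.239 ± 0.206, 70.6 ± 15.4, 66.3 ± 9.74 and 216 ± 21 CPM in wild-type saline, wild-type glycine, knockout saline and knockout glycine.

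Endothelial lists also differed, endothelial identity and angiogenesis by members too weak to pass singly. Endothelial identity had a median difference of 0.88 (adjusted p = 5.82e-07, and adjusted p = 0.207 with an estimated correlation) and angiogenesis 1.07 (0.000267, and adjusted p = 0.0977 with an estimated correlation), with Kdr nearest (1.75 ± 0.41 SE, adjusted p = 0.0572). In the lymphatic list 2 of 10 passed (median 1.06, adjusted p = 0.000107, and adjusted p = 0.0464 with an estimated correlation), with Ccl21a at 2.01 ± 0.26 (0.00200). Between the glycine effects of both genotypes the correlation over all genes was 0.05. They shared 14 rises (1.28 if genes were independent, Fisher p = 3.33e-11) and 1 fall (0.111 if independent), while 10 of the 25 genes called in both went in opposite directions. Genes that move together are not independent, so this Fisher p is too small.

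**Figure D3:**
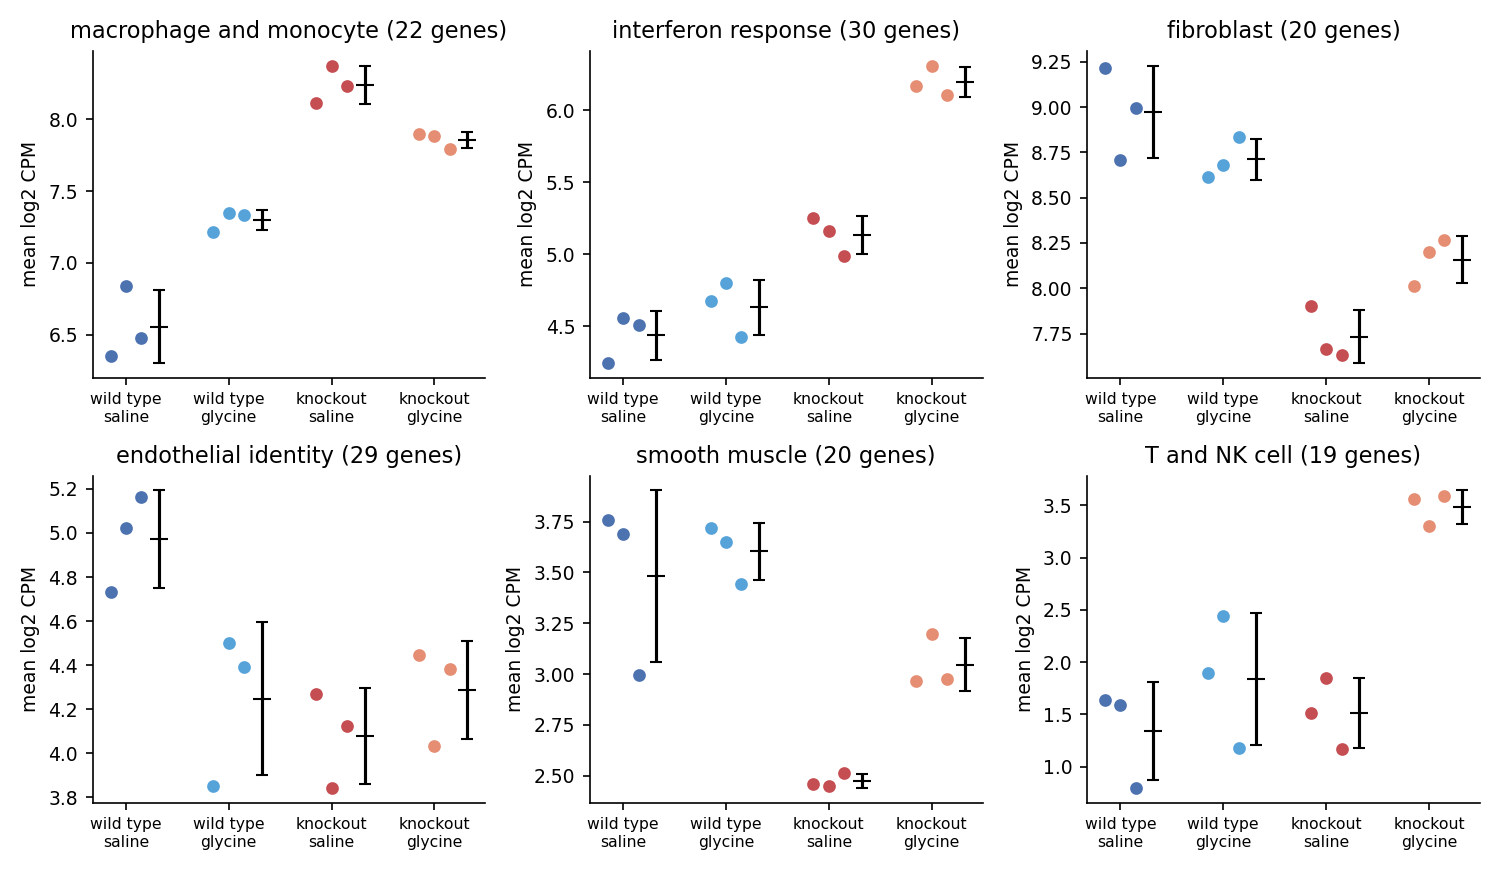
Mean log2 CPM of the members of 6 gene lists in the 4 groups; each point is 1 library, the black bar the mean ± SD of 3. The macrophage list rises from 6.56 to 7.30 with glycine in wild type and drops from 8.24 to 7.86 in knockout, and the interferon list is highest in knockout glycine (6.19).

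What does deletion of Glra2 change under saline? Most macrophage and neutrophil genes of the lists rose (20 of 22 and 11 of 17) and most fibroblast genes fell (15 of 20). Ctss, Fcgr3, Lyz2 and Cd68, which serve phagocytosis and lysosomal digestion, all rose. Lum, Ccdc80 and Postn, made by fibroblasts, and Acta2 and Tagln, contractile genes, fell. The endothelial receptors Kdr and Tek and the transcription factor Ets1 fell with them, though the smooth muscle and endothelial lists do not pass with an estimated correlation (adjusted p = 0.0977 and adjusted p = 0.174).

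It was the largest comparison, with 1573 genes called (841 higher, 732 lower), 3268 at unadjusted p below 0.05 and 1223 changed at least 2-fold. Rises were 53.5% of the calls on counts and 77.1% on FPKM (1208 of 1567), with a median shift of 0.20 log2 on FPKM. Without knockout saline 2 the number was 1016.

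In the macrophage list 20 of 22 members rose (21 over the list alone; median 1.69, adjusted p = 7.32e-28, and adjusted p = 0.0335 with an estimated correlation). Ctss (ENSMUSG00000038642), cathepsin S, rose from 456 ± 103 to 2182 ± 214 CPM (log2 fold change 2.26 ± 0.16 SE, adjusted p = 1.11e-06). Fcgr3 rose by 1.63 ± 0.14 (5.09e-06), Lyz2 by 1.96 ± 0.18 (1.16e-05) and Cd68 by 1.79 ± 0.17 (1.22e-05). Spp1, osteopontin, rose from 49.4 ± 12.1 to 1571 ± 894 CPM (4.99 ± 0.36, 1.11e-06). Neutrophil genes rose in 11 of 17 cases (13 over the list alone; median 2.2, adjusted p = 6.74e-10, and adjusted p = 0.0464 with an estimated correlation), among them Mmp8 (2.86 ± 0.50, 0.00149) and Cxcr2 (2.2 ± 0.38, 0.00137). Camp and Cd177, also neutrophil genes, had 0 counts in wild-type saline and were at least 67.2-fold and 230-fold higher. Among other genes with the largest rises, Gpr82 (adjusted p = 0.00573), Relt (0.00167) and Igha (1.53e-08) kept their calls in all leave-one-out fits, and Spint1 (0.0153) lost it in 2 (highest 0.0588, without wild-type saline 1). KEGG Lysosome had 43 genes higher and 5 lower of 122.

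Genes of the oxidative burst and of inflammation rose in the same libraries. Ncf4 (ENSMUSG00000071715), a subunit of the phagocyte NADPH oxidase, rose from 46.9 ± 6.77 to 319 ± 34.2 CPM (log2 fold change 2.77 ± 0.17 SE, adjusted p = 3.63e-07) and Cybb by 1.83 ± 0.19 (3.43e-05). In the oxidative stress list 10 of 26 rose and 1 fell (12 and 2 over the list alone; median 0.60, adjusted p = 1.10e-05, and adjusted p = 0.0932 with an estimated correlation). The adhesion and NF-kB list had 7 of 29 higher, with Tnf (3.02 ± 0.49, 0.000843) and Il1b (1.82 ± 0.31, 0.00123), and 1 lower (list adjusted p = 0.0450, and adjusted p = 0.560 with an estimated correlation; a call lost when any of 9 libraries was left out). Glycolysis genes such as Pkm (1.04 ± 0.17, 0.00104) rose in 6 of 25 hypoxia and glycolysis members (14 over the list alone; median 0.56, adjusted p = 5.13e-05, and adjusted p = 0.0977 with an estimated correlation). The interferon list had 6 of 30 higher, including Oas1a (1.22 ± 0.18, 0.000364, list adjusted p = 0.00683, and adjusted p = 0.296 with an estimated correlation). Erythroid genes rose in 3 of 15 cases (median 1.21, adjusted p = 0.00285, and adjusted p = 0.382 with an estimated correlation), where the haemoglobin share was 4.51 ± 1.75% against 1.5 ± 0.411%.

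Fibroblast genes fell in 15 of 20 cases (19 over the list alone; median −1.41, adjusted p = 1.27e-20, and adjusted p = 0.0464 with an estimated correlation). Ccdc80 fell from 2949 ± 933 to 653 ± 26.4 CPM (log2 fold change −2.18 ± 0.21 SE, adjusted p = 1.40e-05) and Lum from 2605 ± 346 to 984 ± 164 CPM (−1.40 ± 0.15, 4.50e-05). In the matrix list 20 of 32 fell and 2 rose (median −1.16, adjusted p = 1.23e-11, and adjusted p = 0.0977 with an estimated correlation), with Postn, periostin, at −1.35 ± 0.19 (0.000272). Smooth muscle genes fell in 8 of 20 cases (9 over the list alone; median −1.21, adjusted p = 0.000102, and adjusted p = 0.0977 with an estimated correlation), led by Acta2 (−1.88 ± 0.22, 7.94e-05) and Tagln (−1.88 ± 0.32, 0.00118). The transition regulators, which share both, had 4 of 24 lower and 2 higher (adjusted p = 0.00767, and adjusted p = 0.0977 with an estimated correlation). The adipocyte gene Cfd fell from 60.2 ± 23.7 to 2.31 ± 1.48 CPM (−4.76 ± 0.42, 6.60e-06, list adjusted p = 0.00585, and adjusted p = 0.213 with an estimated correlation). The largest falls included Necab1 (0.00999), Zfp982 (0.0199), Stbd1 (0.0401), Map7 (0.0363) and Rab6b (0.0130); Rab6b kept its call in all leave-one-out fits, and the others lost theirs in 1, 2, 3 and 4 of 6. The highest adjusted p were 0.0529 without wild-type saline 3, 0.0833 without knockout saline 3, 0.162 without wild-type saline 1 and 0.0986 without knockout saline 1.

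Endothelial identity genes fell in 7 of 29 cases (12 over the list alone; median −0.85, adjusted p = 4.43e-08, and adjusted p = 0.174 with an estimated correlation). Kdr fell from 114 ± 37.7 to 41.2 ± 15.4 CPM (log2 fold change −1.48 ± 0.29 SE, adjusted p = 0.00382), Tek by 1.57 ± 0.30 (0.00283) and Clec14a by 1.27 ± 0.24 (0.00250). Cdh5 fell by 1.74 ± 0.44 (0.0168), a call lost without wild-type saline 2, knockout saline 2 (0.0865) or knockout saline 3, and Pecam1 did not pass (−0.62 ± 0.21, 0.0756). In the angiogenesis list 8 of 27 fell (10 over the list alone; median −0.97, adjusted p = 7.11e-06, and adjusted p = 0.0584 with an estimated correlation), with Ets1 at −2.36 ± 0.35 (0.000479) and Angpt2 at −1.81 ± 0.28 (0.000650). Lymphatic genes fell in 5 of 10 cases (median −1.23, adjusted p = 0.000250, and adjusted p = 0.0464 with an estimated correlation); Pdpn, podoplanin, also made by fibroblasts, fell from 124 ± 33.3 to 16.4 ± 0.812 CPM (−2.92 ± 0.22, 1.86e-06).

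Vasodilation genes moved in both directions. Of 42, 4 rose and 7 fell, and the list did not pass (0.321): Arg1 (log2 fold change 4.97 ± 0.71 SE, adjusted p = 0.000327), Ednrb (1.95 ± 0.29, 0.000423) and Ptgs2 (1.73 ± 0.27, 0.000673) rose and the endothelin receptor gene Ednra fell (−2.19 ± 0.36, 0.000915). In the shear-responsive list, which did not pass (0.169), 5 of 25 fell, including Klf4 (−1.23 ± 0.26, 0.00555), and Hmox1 rose (1.77 ± 0.27, 0.000619). The channel list (0.95) had 2 higher, among them the purinergic channel gene P2rx4 (1.36 ± 0.17, 0.000134). Immediate-early and heat-shock genes split 6 higher and 3 lower (0.118), with Ier3 up (1.99 ± 0.32, 0.000737) and the chaperone gene Hsph1 down (−1.82 ± 0.21, 7.64e-05). The mitochondrially encoded genes shifted down with none passing (median −0.64, adjusted p = 4.23e-05, and adjusted p = 0.443 with an estimated correlation).

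What does deletion change under glycine? In the interferon list 19 of 30 members rose (list adjusted p = 0.0165 with an estimated correlation). Ifit3, Zbp1 and Ifi47, all induced by interferon, rose. Myh11 and Acta2, both of contractile smooth muscle, fell, Acta2 in all but 2 of 6 leave-one-out fits (highest 0.0602, without knockout glycine 4), though the smooth muscle list does not pass with an estimated correlation (adjusted p = 0.207). No endothelial identity gene passed.

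Here 357 genes passed (209 higher, 148 lower), with 1919 at unadjusted p below 0.05 and 269 changed at least 2-fold. Rises were 58.5% of the calls on counts and 80.2% on FPKM (469 of 585). Calls numbered 194 without wild-type glycine 5, 139 without wild-type glycine 6, 190 without knockout glycine 4, 179 without knockout glycine 5 and 186 without knockout glycine 6.

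In the interferon list 19 of 30 members rose (25 over the list alone; median 1.44, adjusted p = 4.04e-35, and adjusted p = 0.0165 with an estimated correlation). Ifit3 rose from 63.3 ± 8.53 to 234 ± 9.36 CPM (log2 fold change 1.89 ± 0.21 SE, adjusted p = 0.000215), Zbp1 by 2.37 ± 0.28 (0.000275) and Ifi47 by 1.48 ± 0.18 (0.000302). The T cell list had 2 of 19 higher (6 over the list alone; median 1.49, adjusted p = 7.89e-09, and adjusted p = 0.0977 with an estimated correlation), with Trbc2 at 2.87 ± 0.37 (0.000770). The immunoglobulin constant genes Ighg2c (4.81 ± 0.50, 8.63e-05) and Igkc (1.49 ± 0.25, 0.00395) rose, in a B cell list with 1 of 17 higher (adjusted p = 0.0104, and adjusted p = 0.444 with an estimated correlation), a list call that ended without wild-type glycine 6. In KEGG Antigen processing and presentation 11 of 62 genes rose.

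Of 22 macrophage genes 3 rose (7 over the list alone; median 0.43, adjusted p = 1.84e-07, and adjusted p = 0.139 with an estimated correlation): Ctss by 1.19 ± 0.16 (log2, SE, adjusted p = 0.000789), Ly6c2 by 2.96 ± 0.42 (0.00155) and Fcer1g by 0.83 ± 0.17 (0.0149; lost in 3 of 6 fits, highest 0.0744 without wild-type glycine 5). The decoy receptor gene Il1r2 was the 1 of 17 neutrophil genes to pass (2.05 ± 0.32, 0.00263; list median 1.08, adjusted p = 5.39e-06, and adjusted p = 0.0977 with an estimated correlation). Proliferation genes moved up (median 0.86, adjusted p = 1.49e-07, and adjusted p = 0.0335 with an estimated correlation), as did nuclear respiratory chain genes (0.41, adjusted p = 1.22e-08, and adjusted p = 0.146 with an estimated correlation) and muscle genes (1.38, adjusted p = 1.95e-10, and adjusted p = 0.139 with an estimated correlation).

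On the falling side, 4 of 20 fibroblast genes passed (15 over the list alone; median −0.65, adjusted p = 5.15e-11, and adjusted p = 0.0977 with an estimated correlation) and 6 of 32 matrix genes (21 over the list alone; −0.83, adjusted p = 4.02e-14, and adjusted p = 0.0834 with an estimated correlation), where Spp1 rose (lost in 2 of 6 fits, highest 0.0668 without wild-type glycine 6). Of 20 smooth muscle genes 2 fell (median −0.75, adjusted p = 0.00943, and adjusted p = 0.207 with an estimated correlation), with Myh11 at −2.43 ± 0.44 (log2, SE, adjusted p = 0.00879). Pdpn fell from 108 ± 21.8 to 20.9 ± 1.13 CPM (−2.38 ± 0.22, 3.87e-05) and Cfd from 160 ± 18.2 to 26.6 ± 1.06 CPM (−2.58 ± 0.36, 0.00149). Shear-responsive genes shifted down, with Tgfb2 passing, a call lost in 3 of 6 fits (highest 0.144, without wild-type glycine 6; list median −0.37, adjusted p = 0.00585, and adjusted p = 0.0834 with an estimated correlation). Endothelial identity (0.569) and angiogenesis (0.290) did not pass, nor did Cdh5 (−0.22 ± 0.43, 0.920) or Pecam1 (−0.14 ± 0.21, 0.881).

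Which genes separate the genotypes whatever the treatment? Eno1b (ENSMUSG00000059040), a retained copy of the glycolytic gene Eno1, rose from 1.76 ± 1.90 to 454 ± 49.9 CPM under saline (log2 fold change 7.91 ± 0.58 SE, adjusted p = 1.18e-06) and from 0.543 ± 0.149 to 268 ± 16.4 CPM under glycine (8.87 ± 0.63, 4.38e-06). Its reads can be shared with Eno1, which fell under glycine (−1.03 ± 0.15, 0.00173), so its level is uncertain. Ifi202b, an interferon-inducible gene, rose under both treatments (8.43 ± 0.66, 1.86e-06 and 6.51 ± 0.59, 3.80e-05), as did Ncf4 (2.12 ± 0.17, 1.21e-05 under glycine). The zinc finger gene Zfp984 (−4.26 ± 0.64, 0.000502 and −3.98 ± 0.62, 0.00279) and the complement receptor gene C5ar2 (−5.14 ± 1.19, 0.01 and −5.34 ± 1.18, 0.0251; under glycine lost in 4 of 6 fits, highest 0.113 without knockout glycine 5) fell under both. Prune2 fell under saline (−2.48 ± 0.36, 0.000352) and, under glycine, from 204 ± 71.9 to 21 ± 9.31 CPM (−3.28 ± 0.37, 0.000215). Under glycine the splicing factor gene Srsf2 fell from 261 ± 91.5 to 30.9 ± 4.73 CPM (−3.08 ± 0.32, 8.63e-05). It was not among the genes called and at least 4-fold apart under both treatments. The other largest rises under glycine were Ighg2b (4.65 ± 0.72, 0.00237), Ighv14-4 (0.0114), Ifit1bl2 (0.0149) and Ighv6-3 (0.0383), the last 3 with calls lost in 1, 2 and 6 of 6 fits (highest 0.0515, 0.0809 and 0.145, all without wild-type glycine 6). The other largest falls were Bend4 (−3.0 ± 0.45, 0.00213), Igkv9-123 (0.0194), Zfp429 (0.0114) and Rabl2 (−3.14 ± 0.60, 0.0109), the last 3 with calls lost in 4, 2 and 2 fits (highest 0.0874 without wild-type glycine 6, 0.0609 without knockout glycine 6 and 0.0585 without knockout glycine 4).

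Both genotype comparisons shared 110 rises (12.6 if genes were independent) and 113 falls (7.78 if independent), with a correlation of 0.26 over all genes. Of the 230 genes called in both, 7 went in opposite directions. The lists never called in any comparison were nitric oxide and vasodilation, glycine receptors, transport and metabolism, calcium channels, cholesterol biosynthesis (smallest adjusted p = 0.525), mesothelial and epithelial genes (0.0716), Schwann cell and neuron genes (0.0545), and sex-linked genes (0.169). Among them Pmp22, a myelin gene, fell with deletion under saline (−1.16 ± 0.20, 0.00149), and the male-specific Ddx3y was level (−0.16 ± 0.19, 0.692).

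**Figure D4:**
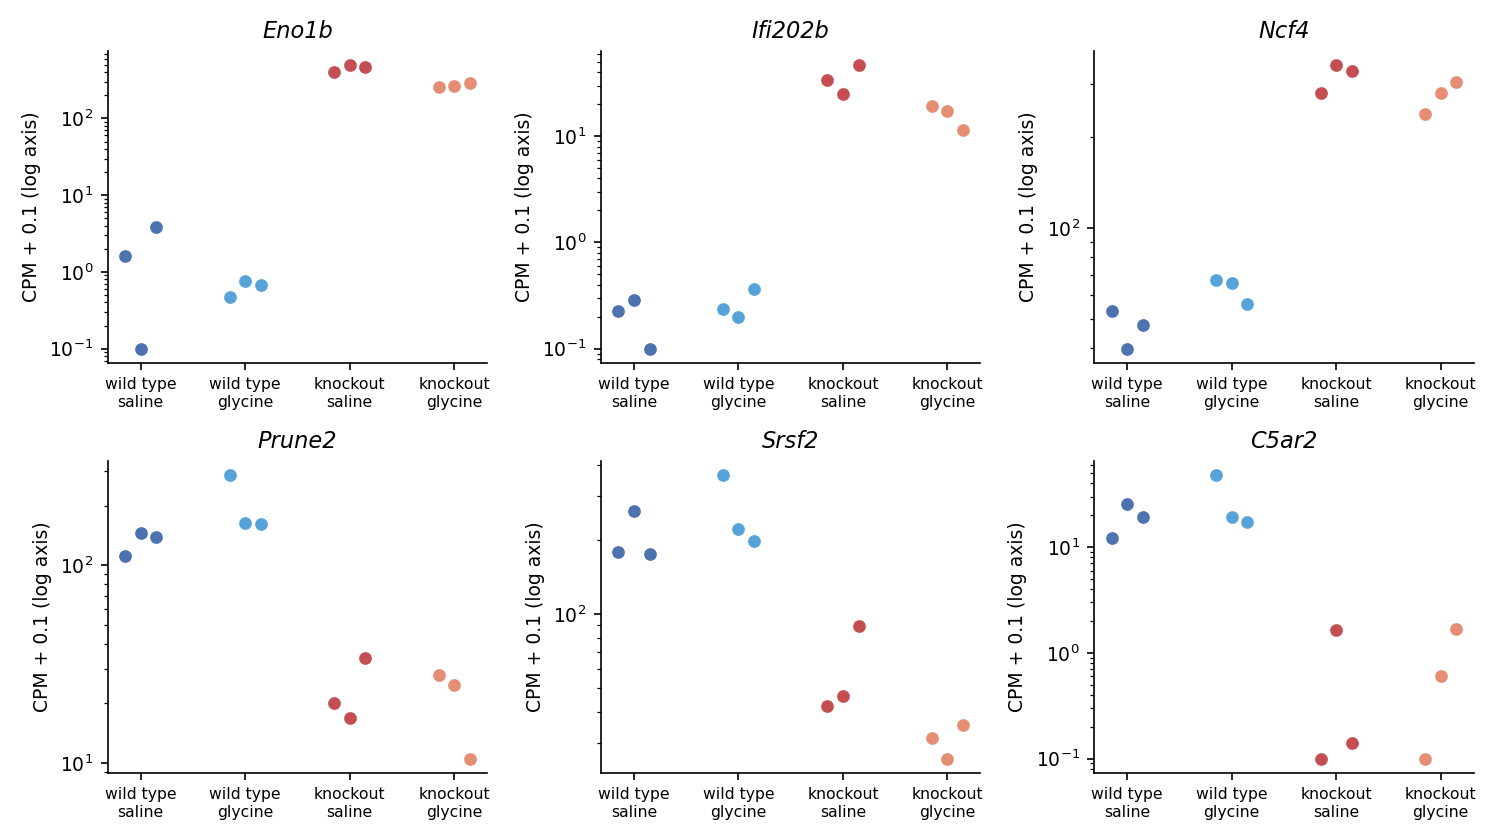
Levels of Eno1b, Ifi202b, Ncf4, Prune2, Srsf2 and C5ar2 (CPM + 0.1, log axis) in the 4 groups; each point is 1 library. Eno1b is at 454 and 268 CPM in knockout saline and glycine against 1.76 and 0.543 CPM in wild type, and Srsf2 drops to 30.9 CPM in knockout glycine.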

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

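The tests of this part, namely the interaction test, the list tests at the preset and the estimated correlation and the exchange of treatment labels, were fixed before the results were seen. What singled out the results of this part is a difference between groups: the glycine effect in knockout minus that in wild type, tested as an interaction. It was called for 156 genes. With treatment labels exchanged within genotype, 2 of 100 assignments, the real one included, gave as many genes, and the highest other number was 219. That excludes, at 1 in 20, that the treatment labels carry no difference in either genotype. Mixed assignments remove both glycine effects as well as their difference, so chance is not excluded for the interaction alone. The assignment with 219 genes exchanges saline and glycine in all knockout libraries and in no wild-type one, so it tests the sum of both glycine effects. The genotype, which the design names, stays open as the source, and the pattern is a hypothesis for new animals.

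By gene, the difference was −6.62 log2 for Igha, 3.59 for Iigp1, 3.23 for Tgtp2, −2.46 for Cfp, −1.87 for Tmem106a and −2.71 for Ms4a4a. By list, the median difference was −1.25 for macrophage and monocyte genes, 1.02 for interferon response, 1.32 for T and NK cell, −0.96 for neutrophil, and −1.99 for erythroid and platelet genes. With an estimated correlation the macrophage and interferon lists stay called (adjusted p = 0.0464 each), and the T and NK cell (0.242), neutrophil (0.235) and erythroid (0.187) lists do not. Vessel lists had medians of 0.88 (endothelial identity), 1.07 (angiogenesis) and 1.06 (lymphatic endothelium), and with an estimated correlation only the lymphatic list stays called (0.0464, against 0.207 for endothelial identity and 0.0977 for angiogenesis). Stromal and muscle lists stood at 0.65 (smooth muscle), 0.69 (fibroblast) and 1.55 (skeletal and cardiac muscle), calls that all end with an estimated correlation (0.268, 0.135 and 0.242). Metabolic and stress lists stood at −0.58 (oxidative stress), −0.35 (unfolded protein response), −0.20 (hypoxia and glycolysis), 0.39 (mitochondrially encoded genes), 0.38 (nuclear respiratory chain) and −0.69 (immediate-early and heat-shock genes). All 6 calls end with an estimated correlation (0.0977, 0.174, 0.284, 0.667, 0.368 and 0.444 in that order).

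For the pairwise comparisons, exchanging libraries between groups leaves only 10 splits of 3 against 3, too few to exclude chance. Only the real split (1 of 10) gave as many genes in each. The real numbers were 193 (glycine in wild type), 157 (glycine in knockout), 1573 (knockout under saline) and 357 (knockout under glycine), and the highest others were 1, 0, 0 and 0.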

How the results depend on the processing

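Gene numbers stayed within 1.5 times of those reported under size factors in place of TMM, both filters and removal of the mitochondrial genes, with the exceptions given here; where values moved, the cause was not tested. With DESeq2 the numbers were 529 (glycine in wild type), 501 (glycine in knockout), 796 (knockout under glycine), 509 (interaction) and 69 for the overlap of the glycine effects, which was 15 as reported and 88 at unadjusted p below 0.01. On FPKM + 1 they were 1099, 703, 585 and 283 in that order, with an overlap of 157; on FPKM + 0.1, glycine gave 1076 and 565, with an overlap of 128. With only the compared groups in the model, glycine gave 31 in wild type and 336 in knockout, with an overlap of 6. The smooth muscle and fibroblast level as a covariate left 0 (glycine in knockout), 0 (knockout under saline), 6 (knockout under glycine), 6 (interaction) and 0 shared. The macrophage level, chosen after the data were seen, left 1 (glycine in wild type), 10, 0, 17, 0 and 0. Where calls were lost, these levels differ between the compared groups themselves. Either covariate then takes up part of the contrast, and the lost calls name no source. Of 81 called lists 13 stayed with an estimated correlation and 55 with fry, and of 230 pathways 0.

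With 1 library left out, numbers ran from 80 to 259 (glycine in wild type), 57 to 123 (glycine in knockout), 1016 to 1491 (knockout under saline), 139 to 391 (knockout under glycine), 60 to 338 (interaction), 75 to 85 (lists) and 8 to 19 (overlap). Named genes kept direction and side in 3622 of 4803 alternatives, lost the threshold in 1122, gained it in 1 (Pecam1 under saline, DESeq2) and reversed in 58. Called lists kept theirs in 989 of 1134. Depth limits the low end: genes under 0.118 to 0.279 CPM amount to 3 counts or fewer, and changes of 2-fold were recovered in at most 22% of simulated genes.

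The replicate number as a block, in a model of the compared groups, gave 1046 genes for knockout under saline and 236 under glycine. Libraries of the same number correlated no more than others (−0.034 to 0.019 under saline, −0.031 to −0.018 under glycine), so the numbers carry no pairing.

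Reversals by left-out library concerned fixed genes that did not pass. With 1 library left out, Pecam1, glycine in wild type, ran from −0.158 to 0.146 (0.127 and 0.146 without wild-type saline 3 and wild-type glycine 4). It was 0.39 and 0.40 on FPKM with pseudocounts 1 and 0.1, where the median of all genes was 0.37 and 0.46. Nos3, glycine in knockout, ran from −0.102 (without knockout glycine 4) to 0.69, with −0.055 without knockout glycine 6. Cdh5, glycine in knockout, ran from −0.142 (without knockout glycine 4) to 0.911. Pecam1, knockout under glycine, ran from −0.291 to 0.046 and Cdh5, knockout under glycine, from −0.742 to 0.0963, both highest without knockout glycine 5. Nos3, knockout under glycine, ran from −0.0823 (without wild-type glycine 4) to 0.847. With the smooth muscle and fibroblast covariate Nos3 there was −0.63, and under saline Psmb8 was −0.59, Pfkl −0.47 and Atp5f1a −0.0886.

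With the macrophage covariate, which removes most of the contrast between genotypes by construction, 44 log2 fold changes reversed. In glycine against saline in wild type these were Pik3r5 at −0.32 and Ccdc80 at 0.16, in knockout under glycine Dpt at 0.0122 and Nos3 at −0.54, and in the interaction Gpx1 at 0.11 and Ccdc80 at −0.37. Under saline, genes higher in knockout turned negative: Gpr82 −2.03, Relt −0.88, Spint1 −5.82, Atp2b1 −0.89, Birc3 −0.89, Cybb −0.36, Gpx1 −0.40, Oasl1 −3.65, Psmb8 −0.42, Atf3 −1.32, Pkm −0.43, Hif1a −1.50, Atp5f1a −0.68, Zfp36 −1.03, Ighm −0.26, Iglc2 −1.20, Trem1 −0.44, Pf4 −0.12, Alas2 −2.07 and Hbb-bt −2.54. Genes lower in knockout turned positive: Ednra 1.64, Tek 1.35, Kdr 0.0821, Jag1 0.0673, Lum 0.14, Postn 0.59, Zeb1 1.77, Fgf2 2.89, Sc5d 0.11, Insig1 0.11, Cald1 0.49, Ccdc80 0.60, Mfap5 0.49, Ebf1 2.0, Pmp22 1.33, Scn7a 0.63, Ncam1 0.19 and Flt4 0.69.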

Other observations

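The lists and tests of this part were chosen after the results were seen, except the test of the mitochondrial share, which was fixed before. Some antibody genes rose in every pairwise comparison. Of 12 measured immunoglobulin constant genes, 5 rose with glycine in wild type, 5 with glycine in knockout, 8 with deletion under saline and 5 with deletion under glycine. Igha, the class of mucosal surfaces, was absent or nearly so in wild-type saline only, and Ighg2c, a class driven by interferon, rose by 3.81 ± 0.49 log2 (SE) with deletion under saline (adjusted p = 0.000155) and by 4.81 ± 0.50 under glycine (8.63e-05).

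Of 13 measured thymocyte genes 3 rose with glycine in knockout and 0 passed the interaction test. Rag1, the recombinase of developing lymphocytes, had 0 counts in wild-type glycine and was at least 157-fold higher in knockout glycine (adjusted p = 0.0287; lost in 5 of 6 leave-one-out fits, highest 0.122 without knockout glycine 5). Dntt, Cd8a and Cd8b1, all expressed in thymocytes, leaned upward with glycine in knockout and did not pass (log2 fold change 5.71 ± 1.82 SE, 5.0 ± 1.44 and 4.72 ± 1.18; adjusted p = 0.184, 0.132 and 0.0762). Of 17 clock genes 1 passed with glycine in wild type, Nr1d1, which rose (2.82 ± 0.65, 0.0479; lost in 5 of 6 fits, highest 0.119 without wild-type glycine 5). Of the 17, 1 rose with glycine in knockout, 1 rose and 4 fell with deletion under saline, and 0 passed with deletion under glycine or in the interaction.

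Under saline, macrophage genes were higher and fibroblast genes lower in knockout. A lower share of endothelial cells alone would raise the genes of all other types. The fibroblast level differed by −1.24 ± 0.14 log2 (SE), but that fall is part of the pattern and cannot test this. The endothelial identity level differed by −0.89 ± 0.21, so a lower share beside other changes stays open. The smooth muscle level, outside the pattern, differed by −1.01 ± 0.19, which argues against a lower endothelial share as the only source. The mitochondrial share of the counts is not the whole source either: the macrophage level differed by 1.68 ± 0.12 without and 1.73 ± 0.18 with that share as a covariate. More macrophages among the collected cells cannot be told apart from a changed state of the same macrophages, since the 20 of 22 members higher only restate the pattern. An effect of the deletion, which the design names, stays open as untested.

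Immunoglobulin variable segments (139) were shared within groups more than between them, and unevenly: the mean correlation within groups was 0.890 in knockout and 0.694 in wild type, and segments over 4-fold above all libraries of other groups numbered 26 in knockout glycine, 3 in knockout saline, 2 in wild-type glycine and 0 in wild-type saline. No minimum level per library was set for these numbers. Ighv3-8 counts with 0.211 CPM in knockout glycine 6 and 0 in the other groups. Antibody levels also differed, with Ighg2b at 1.03 CPM in wild-type saline and 152 in knockout glycine. The unevenness therefore cannot be told apart from the level of these genes and noise near 0 counts. Chance arrangement of all 12 libraries is excluded, as 1 of 15400 partitions, the real one, reached the mean correlation of 0.792 (highest other 0.756), but not within a genotype, where 1 of 10 splits, the real one, is too few to tell; general likeness of libraries is excluded over all groups by 0 of 1000 random gene sets with as large an excess (0.328, highest other 0.143) and in knockout by 0 of 1000 (0.511, highest other 0.141), and stays undecided in wild type, where 1 of 1000 reached 0.135. By these segments, one RNA pool split in 3 cannot be told apart from separate samples in any group. Segments over 4-fold higher in 1 library than in both others numbered 4 (wild-type saline), 15 (wild-type glycine), 7 (knockout saline) and 2 (knockout glycine). Outside the library with the most they numbered 2, 4, 0 and 1, too few by a bound set after these values were seen. Over genes with sufficient counts, libraries of a group differed by a chi-square of at least 35.1 per degree of freedom, far above counting error. That argues against 1 library sequenced 3 times. The noise between preparations of one pool is not known here, so one pool prepared 3 times stays open. In knockout glycine the lower dose label of library 5, if right, argues against one pool. Different germline segments in both genotypes, as the only source of the sharing, are argued against in knockout. There the highest correlation between treatments was 0.506 and the lowest within a group 0.838, though in wild type those values were 0.665 and 0.543. Some segments differed between genotypes under both treatments. Igkv6-32 was higher in knockout (log2 fold change 4.71 under saline and 4.54 under glycine) and Igkv9-123 was lower (−6.12 and −7.28). Germline differences beside other sources therefore stay open. What also stays open is a shared source of B cells per group, such as cage, litter or day of collection, which no label gives and no test here addressed.

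Between genotypes, 42 genes were at least 4-fold apart in the same direction under both treatments (28 higher, 14 lower). A chromosome X segment carried along with the targeted allele is argued against as the source of most of this set, as 0 of the 42 lie on chromosome X, where Glra2 lies. Of 44 tested genes near it, 0 were called alike in both genotype comparisons. On the other chromosomes only 1.61% of genes were called so, too few for the 0 of 44 to tell. A segment with few changed genes stays open. Reads of Eno1 counted as Eno1b cannot be told apart from a real change, since the sum of both genes was 2.51-fold higher under saline and 1.31-fold under glycine. A difference in strain background likewise stays undecided: genes called alike formed 11 neighbouring pairs against 3.52 on average and 12 at most in permuted orders, but 4 pairs when genes with like names are left out, a wording chosen after the first value was seen. The strain is not given in the sources used here, and an effect of the deletion stays open as untested.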
